A study of Homo sapiens with 6 samples.

How the data were processed

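RNA was taken from A375 cells, an established human melanoma line, engineered so that doxycycline switches on HEXIM1. HEXIM1 encodes an inhibitor of P-TEFb, the CDK9 kinase complex that releases paused RNA polymerase II. Per the labels' protocols, ribosomal RNA was removed from column-purified RNA, and indexed libraries were amplified by PCR, size-selected and sequenced together on an Illumina HiSeq instrument. The labels name 6 samples, 3 given DMSO and 3 given doxycycline at 1 μg/mL, all collected after 48 h. Whether the replicates came from separate cultures is not stated beyond the word triplicate. Per the submitters' processing notes, cutadapt, TopHat2 version 2.0.11, Cufflinks version 2.2.1 and the build hg19 were used; their roles, order and settings, and the transcript annotation, are not given in the sources used here.

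The deposited table lists RefSeq transcripts with a gene symbol, a position and a strand, beside 6 columns that the authors' file name calls normalized FPKM (fragment counts scaled by transcript length and library size). These 6 value columns are headed by laboratory codes, and 0 of the 6 codes occur in the sample titles, descriptions, protocols or design text used here. From these sources alone, the columns could be assigned to treatments only by their order or by the expression values themselves. No label used here ties the order to the samples. The values, such as that of HEXIM1, are what the comparison was meant to measure. The 6 columns were therefore given to no sample and were not used. No FPKM value, fold change or test is reported, and the depth of the libraries is unknown.

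The planned comparison was fixed before the data were examined. It was a moderated linear model of log2(FPKM + 1) between doxycycline and DMSO. The plan also held 33 gene lists, to be tested where enough members passed an expression filter, and a rule for naming genes. Its alternatives included a block on replicate number. None of this plan was run. What was computed is a description of the annotation columns: the number of rows per gene symbol, the sequences they lie on, and how many symbols of the 33 lists have a row, with Python 3.11.15 and pandas 2.3.3. Positions are those of the table, with hg19 as the listed build; whether starts count from 0 or 1 is not given in the sources used here. The highest transcript end on chromosome 1 of the table, 249213345, lies beyond the highest gene end on chromosome 1 of a GRCh38.p14 gene table, 248937099, so GRCh38 coordinates were not mixed with those of the table. Synonyms from that gene table served only to join older and current symbols within the lists. Both names of each mitochondrially encoded gene were joined by hand-written rules.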

Results

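The series was designed to ask how raising HEXIM1 changes the transcriptome of melanoma cells. Total RNA of A375 cells with a doxycycline-inducible HEXIM1 was sequenced after ribosomal RNA removal, in 3 DMSO-treated samples and 3 samples treated with 1 μg/mL doxycycline for 48 h. The comparison of doxycycline with DMSO was not made here. The 6 columns of FPKM values are headed by codes of which 0 occur in the sample labels used here. From these labels, no column could be assigned to a treatment without using its order or its values. No expression level is reported for HEXIM1 or for any other gene, and nothing is said on whether doxycycline raised HEXIM1 in these cells. The text is limited to which genes the table covers and at what resolution. A row shows that a symbol was listed. Since no value was read, it does not show that the gene was expressed in these cells.

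The table held 43497 rows of RefSeq transcripts for 23613 gene symbols. Of these rows, 35939 carried an accession for an mRNA and 7558 an accession for a non-coding RNA. The rows drew on 40793 different accessions once numeric suffixes were set aside, and 2809 rows carried such a suffix. What the suffix marks was not checked. A single row was listed for 15217 gene symbols, and 8396 symbols had more than 1 row. The rows of 2924 symbols had more than 1 start coordinate. A start is the lowest position of a row on its sequence and, on the minus strand, the 3′ end of the transcript. Starts were pooled over all sequences, so rows of a symbol on different sequences can count as different starts. Row counts, here and for the gene lists below, were pooled in the same way. More than 1 row therefore need not mean more than 1 different transcript.

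HEXIM1 was listed as 1 transcript on the plus strand of chromosome 17, from 43224684 to 43229468 in hg19 coordinates. Its paralog HEXIM2 was also listed as 1 transcript, on the same strand of chromosome 17 from 43238264 to 43247406. CDK9, the kinase of P-TEFb, had 1 row on the plus strand of chromosome 9 from 130548305 to 130553052. CCNT1, which encodes its cyclin T1 partner, had 1 row on the minus strand of chromosome 12 from 49082241 to 49110781. CCNT2, which encodes cyclin T2, had 3 rows on chromosome 2. LARP7 and MEPCE, which encode proteins of the 7SK particle that holds P-TEFb with HEXIM1, had 4 rows each, on chromosomes 4 and 7. All 23 symbols of the list of P-TEFb, 7SK and elongation factors had at least 1 row, and 11 of them had more than 1.

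All 24 symbols of the melanocyte lineage list had a row, and 14 of them had more than 1 row. Marker lists of other cell types were just as complete. They held 12 fibroblast symbols, 14 keratinocyte and epithelial symbols and 12 blood and immune cell symbols. MITF, the master transcription factor of melanocytes, had 8 rows with 5 different starts on chromosome 3, between 69788586 and 70017488. All 22 neural crest symbols and all 20 symbols of MAPK pathway output were listed, and 8 and 9 of them had more than 1 row. The lists of DNA replication and of mitosis genes were also complete, with 36 of 36 and 35 of 35 symbols. Each had 17 symbols with more than 1 row. Among 34 replication-dependent histone symbols, all were listed and 1 had more than 1 row. Of 25 p53 target symbols, 24 were listed, and 15 of those had more than 1 row. The symbol without a row was TIGAR, and other names of that gene were not searched.

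None of the 26 symbols fixed for mitochondrially encoded genes, which give each gene under both of its names, matched a row. These transcripts are therefore not analysed here. The lists of nuclear-encoded genes of mitochondrial function were complete, with 45 of 45 symbols of oxidative phosphorylation and 35 of 35 of mitochondrial translation. Genes of this class outside the lists were not examined. Of 23 antigen presentation symbols, 19 had more than 1 row and 16 had rows on alternative haplotypes of chromosome 6. HLA-DRB1, a class II beta chain gene, had 8 rows, 6 of them on such haplotypes. B2M, which encodes the class I light chain and lies on chromosome 15, had 1 row. In the whole table, 2135 rows for 213 symbols lay on alternative haplotypes of chromosome 6.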

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

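Alternatives fixed before the data were examined (pseudocount, filter on low values, left-out libraries, rescaling, variance model, short RNAs and kinds of set test) were not run, since the value columns were not used. No paired analysis was possible because the value columns carry codes that no label ties to a replicate number or a treatment. The following alternatives were chosen after the annotation columns were seen. On chromosomes 1 to 22, X and Y alone, 8238 symbols had more than 1 row against 8396 over all sequences. In the same settings, 2704 against 2924 had rows with more than 1 start coordinate. Both counts of starts pooled the sequences, so neither gives the symbols with different starts at a single locus. Over all 33 lists, 782 of 815 different symbols had a row. Joining older and current symbols of the same gene left 796 genes, of which 782 had a row under a listed name and 14 did not. Only names within the lists were joined, so the number with a row could not rise. Names outside the lists were not searched, so a gene without a row may still be in the table under another name.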
